A study of Mus musculus with 11 samples.

How the data were processed

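RNA was sequenced from the synovial membrane of DBA/1 mice in 11 libraries: 3 of sham and 3 of CIA mice on the regular diet, and 2 of sham and 3 of CIA mice on the high-fat diet. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an in-house kit of the sequencing provider. Whether the kit marks strand is not stated, so reads of a gene and of an antisense partner cannot be told apart. One deposited table of 18804 coding genes, all of 1 gene type, held every value used. Per the file headers, the authors gave estimated counts per gene and library. These expected counts are not normalized, and 11.98% of them were not whole at a tolerance of 0.001. The authors also deposited FPKM values (scaled by gene length and depth) and TPM values (scaled to the same total per library), per the file headers. The authors' deposited table further holds a log2 fold change and a DESeq2 q-value (an adjusted p-value) for each gene in 4 comparisons. The submitters' processing notes list Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and the genome GRCm38.p6, without saying which step each served. Of the table's chromosome positions, 1.77% of genes have the start that RefSeq gives for GRCm38.p6, and the reason was not tested. Positions printed here are therefore those of RefSeq's GRCm38.p6 annotation, matched by NCBI gene ID for 18663 of the 18804 genes. All 11 count columns were matched to a sample by name.

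Expected counts were rounded to whole numbers. Of the 18804 genes 507 had no count in any library, and 1 further line of the table was empty. edgeR's filterByExpr left 14892 genes, which were scaled with TMM and fitted with edgeR's quasi-likelihood model (glmQLFit, robust) with 1 mean per group. All 11 libraries entered the fit, because high-fat sham has 2. The contrasts were CIA against sham on each diet, high-fat against regular diet in sham and in CIA mice, and the difference between both CIA effects (interaction). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A value given as a number ± another after a gene's name is the log2 fold change ± SE. This SE was not fitted directly. It was derived from the quasi-likelihood F test, as the absolute log2 fold change divided by the square root of F. Counts-per-million (CPM) use TMM-scaled totals and are given as mean ± SD, and log2 CPM used a prior count of 2. All p-values are two-sided, except those of the enrichment tests. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

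The contrasts, tests, gene lists, naming rule and most alternatives were set before the data were examined. There were 41 gene lists of pathways, of cell types that the dissected tissue could hold and of sample quality. The 40 with at least 5 members among the tested genes were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over lists within each contrast, and again with an estimated correlation and with limma's fry. The list of mitochondrially encoded genes had 0 of 26 members among the tested genes. For the members of a list, calls are given over all genes and adjusted over the list alone. A list's median was also computed with members that have no count in a group set to a bound of 3 counts per library of that group, at the mean library size. Such bounds cover counting error only.

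Genes were named by rule. In each contrast these were, among called genes with a named symbol, a mean log2 CPM of 1 or more and no overlap between the groups, the 6 rising and 6 falling ones with the largest change. Up to 4 called members of each list were added, and for lists with at most 1 called member up to 2 of the most abundant members, as values. Tnf, Il6, Il1b, Il17a, Mmp3, Mmp13, Prg4, Lep, Adipoq, Acta1, Ckm and Col2a1 could always be named as values. Not all genes that qualify are named, some of them are not reported here, and genes outside the rule are named as chosen after their values were seen.

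The alternatives were DESeq2, limma voom, RLE and upper-quartile scaling, no filter on low counts, a filter of CPM of 1 or more in 3 libraries, and the replicate letter as a block. The others were leaving out the 20 most abundant genes, a threshold of 1 on the absolute log2 fold change, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), a fit of only the groups compared, and leaving out each library in turn. After the data were seen, the mean log2 CPM of the adipocyte list or of the skeletal muscle list was added as a covariate, the effects of diet and CIA were averaged over the other factor, and called genes were tested for enrichment of the KEGG terms that the deposited table gives.

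Total counts were 13677638 to 17631167 per library. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 19.1 to 278.5, so precision rests on this spread and on few libraries per group. Counts were simulated with each gene's mean over all 11 libraries, its fitted spread and the library sizes. The fit was tested on these, with 200 genes changed in each comparison. Of the genes simulated at folds of 2, 4 and 8 it recovered 8.96%, 67.2% and 83.3% for CIA against sham on the regular diet, 5.97%, 65.7% and 87.9% on the high-fat diet, 8.96%, 47.8% and 80.3% for diet in sham mice, and 8.96%, 59.7% and 74.2% for diet in CIA mice. The genes tested were 14745, 14738, 14733 and 14735, and unchanged genes called were 7, 4, 3 and 3. In these simulated counts, folds near 2 were mostly not detected. Every group was given the same spread, genes were independent and no library stood apart, so recovery in the data may be lower. Between diets in sham mice Elovl6 did not pass, at 20 and 22.5 CPM on the high-fat and 367, 345 and 396 on the regular diet. Some members of the Serpina3, MHC class II and globin families resemble each other in sequence, so the split of reads among those may be uncertain, which was not tested.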

Results

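Gene expression was measured by RNA sequencing in the synovial membrane, the tissue that lines the joint, of DBA/1 mice. This inbred strain is prone to collagen-induced arthritis (CIA), in which immunisation against type II collagen leads to inflamed joints, and sham mice serve as controls. The treatment labels also give a regular or a high-fat diet. The growth notes conflict with them, since they give a regular diet for all 11 samples, including the 5 labelled high-fat. Groups follow the treatment labels, and every comparison of diets below rests on these being right. The 11 libraries thus fall into 4 groups: regular-diet sham (n = 3), regular-diet CIA (n = 3), high-fat sham (n = 2) and high-fat CIA (n = 3). The series set out to learn whether obesity changes arthritis. The total count was 13677638, 16096367 and 15778620 in regular-diet sham replicates a, b and c. It was 16218736, 14319731 and 16302601 in regular-diet CIA replicates a, b and c. High-fat sham replicates a and b had 17631167 and 17078251 counts, and high-fat CIA replicates a, b and c had 17233521, 15873010 and 16033565. The labels do not say that the replicates are separate mice, so p-values measure only the spread between these samples, which may be technical. No pair of replicates agreed within counting noise, with a chi-square per degree of freedom of 19.1 to 278.5 over genes.

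The first principal component of log2 counts-per-million (CPM) held 60.3% of the variance. The 3 high-fat CIA libraries lay at 80, 51.5 and 32.4 on it, and the 5 sham libraries of both diets between -42.9 and -13.1. Regular-diet CIA replicate b lay at 47.3, among the high-fat CIA libraries, while replicates a and c lay at -16.9 and -26.1. Across genes, replicate b correlated with a and c at r = 0.905 and 0.888, against 0.982 between a and c. It also held more RNA of inflammatory genes. Il1b, a cytokine that drives joint inflammation, stood at 163 CPM in b against 4.8 and 1.93 in a and c. Mmp3, a protease that degrades cartilage matrix, stood at 1610 CPM against 57.6 and 12.3.

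**Figure D1:**
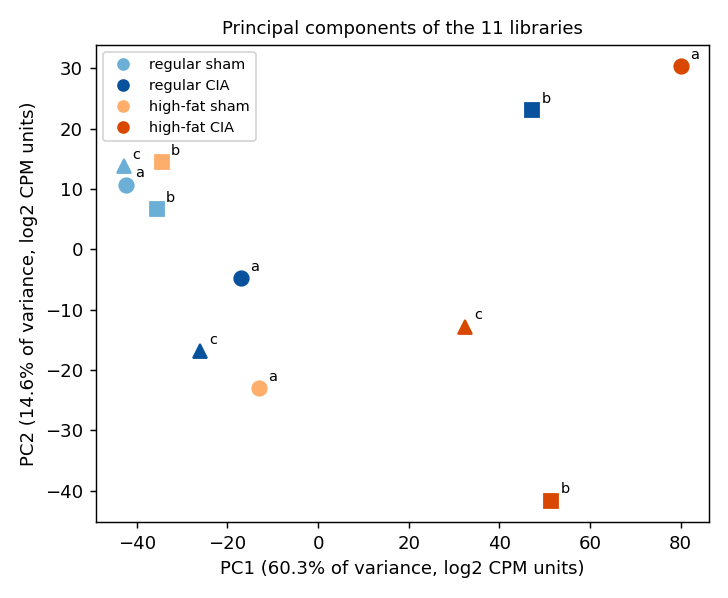
Principal components of the 11 libraries on log2 CPM, with the share of variance on each axis, colour for the group and the letter for the replicate. High-fat CIA libraries and regular-diet CIA replicate b lie at 32.4 or above on the first component, and all other libraries at -13.1 or below.

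The first comparison asked which genes differ between CIA and sham mice on the regular diet. The serine protease inhibitor gene Serpina3i rose from 1.33 ± 0.221 to 19.0 ± 5.29 CPM (SD, n = 3 in each group, log2 fold change 3.83 ± 0.38 SE, adjusted p = 0.0107 in edgeR). Its gene (ID 628900) lies beside Serpina3g (3.94 ± 0.47, adjusted p = 0.0266) and Serpina3f (5.50 ± 0.65, adjusted p = 0.0266), which rose as well. These 3 genes lie on chromosome 12 from 104214544 to 104269509 (GRCm38.p6). They belong to the same family of similar genes, so how reads were shared among them is uncertain. They are among the 4 genes past an adjusted p of 0.05 of 14892 tested. At an unadjusted p under 0.05 there were 2579 genes, where 745 are expected by chance.

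Of the fixed gene lists, those of MHC class II, interferon response, neutrophils, T and natural killer cells and macrophages rose and mast cell markers fell, with 0 members past the test over all genes. All 10 genes of the MHC class II list, which covers antigen presentation to T cells and its regulation, were higher, and 10 passed adjusted over the list alone (median 1.21, adjusted p = 9.34e-11, adjusted p = 0.344 with an estimated correlation). H2-Aa, a chain of the class II molecule, stood at 192 ± 18.9 CPM in sham and 522 ± 145 in CIA (SD, n = 3 in each group, log2 fold change 1.45 ± 0.24 SE, adjusted p = 0.119). All 20 type I interferon response genes were higher, and 10 passed adjusted over the list alone (median 1.11, adjusted p = 5.60e-09, adjusted p = 0.393 with an estimated correlation). Neutrophil markers were higher in 15 of 15 members, 7 of them past the test adjusted over the list alone (median 2.60, adjusted p = 2.60e-05, adjusted p = 0.548 with an estimated correlation). The 19 markers of T and natural killer cells were all higher, 5 of them adjusted over the list alone (median 1.72, adjusted p = 6.63e-08, adjusted p = 0.344 with an estimated correlation). The T and natural killer cell median was 1.58 with the 1 member that had no count in a group set to a bound of 3 counts, and 1.05 without regular-diet CIA replicate b. The mean log2 CPM of this list was -1.09 in sham and 0.25 in CIA, near the floor, so the size of its change is uncertain.

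Macrophage and monocyte markers were higher in 14 of 17 members, 5 of them adjusted over the list alone (median 0.65, adjusted p = 0.00117, adjusted p = 0.393 with an estimated correlation), with a median of 0.32 without regular-diet CIA replicate b. Mast cell markers fell as a list, with 5 of 8 members lower, and 3 lower and 1 higher adjusted over the list alone (median -0.87, adjusted p = 0.0127, adjusted p = 0.344 with an estimated correlation). This was 1 of 3 lists that fry called (adjusted p = 0.0223). With camera it did not pass without regular-diet sham replicate c (-0.77) or regular-diet CIA replicate b (-0.49). Markers of B cells (median 0.14, adjusted p = 0.873) and plasma cells (median -0.21, adjusted p = 0.522) did not pass.

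Cytokine, matrix and protease lists passed only with regular-diet CIA replicate b included, and the median of chemokines shrank without it. Inflammatory cytokines rose, 5 of 17 adjusted over the list alone (median 2.23, adjusted p = 0.00656, adjusted p = 0.638 with an estimated correlation), but had a median of 0.07 and did not pass without that replicate. Chemokines rose, 7 of 22 adjusted over the list alone (median 1.97, adjusted p = 0.000101, adjusted p = 0.393 with an estimated correlation), and passed at a median of 0.73 without it. Collagen and matrix genes (median 0.82, adjusted p = 0.000368, adjusted p = 0.637 with an estimated correlation) and matrix-degrading proteases and inhibitors (median 0.76, adjusted p = 0.0324, adjusted p = 0.393 with an estimated correlation) rose with 1 member each past the test adjusted over the list alone. Without replicate b their medians were 0.30 and 0.27 and neither passed. Chondrocyte markers, of cartilage cells, rose as well, 14 of 14 higher and 3 adjusted over the list alone (median 1.92, adjusted p = 0.0282, adjusted p = 0.649 with an estimated correlation). They did not pass without regular-diet sham replicate b (1.67) or regular-diet CIA replicate c (0.13). Mmp3 had a log2 fold change of 3.85 ± 1.39 (adjusted p = 0.216), and -0.15 without regular-diet CIA replicate b. Il1b had one of 5.58 ± 1.61 (adjusted p = 0.185), and 1.52 without it. Il6, another inflammatory cytokine, had 0.126, 16 and 0.193 CPM in regular-diet CIA replicates a, b and c, and 0.159, 0.0635 and 0.131 in regular-diet sham. The cytokine list had a mean log2 CPM of 0.17 in regular-diet sham, near the floor, so the size of its change is uncertain.

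Lists tied to mitochondria, protein folding, red cells, muscle, fat and ribosomes fell on the regular diet, with 0 members past the test over all genes. All 24 nuclear genes of oxidative phosphorylation, the cell's aerobic ATP production, were lower, 11 of them adjusted over the list alone (median -0.67, adjusted p = 9.34e-11, adjusted p = 0.396 with an estimated correlation). The 12 heat shock genes, which encode protein-folding chaperones and were fixed as a list of sample quality, were lower, 4 of them adjusted over the list alone (median -0.46, adjusted p = 0.000522, adjusted p = 0.344 with an estimated correlation). Erythroid genes were lower in 12 of 12 members, 0 of them adjusted over the list alone (median -2.34, adjusted p = 0.000217, adjusted p = 0.638 with an estimated correlation). The list had a median of -1.49 without regular-diet sham replicate a, and did not pass without regular-diet CIA replicate b (-1.88). Skeletal muscle genes, which mark tissue next to the joint, were lower in 23 of 24 members, 0 of them adjusted over the list alone (median -3.49, adjusted p = 0.000532, adjusted p = 0.649 with an estimated correlation). This list had a median of 0.39 without regular-diet sham replicate c. In that library the actin gene Acta1 stood at 144 CPM, against 0.954 and 1.02 in replicates a and b.

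Fat cell and fatty acid oxidation lists fell on the regular diet only with regular-diet CIA replicate b included. Adipocyte markers were lower in 15 of 17 members, 0 of them adjusted over the list alone (median -0.62, adjusted p = 0.00296, adjusted p = 0.649 with an estimated correlation), lipolysis genes in 15 of 17, 1 adjusted over the list alone (median -0.43, adjusted p = 0.000703, adjusted p = 0.649 with an estimated correlation), and fatty acid oxidation genes in 16 of 21, 0 adjusted over the list alone (median -0.46, adjusted p = 0.00325, adjusted p = 0.649 with an estimated correlation). Their medians were -0.24, -0.09 and -0.12 without replicate b, where none passed, and -1.09, -0.71 and -0.77 without regular-diet CIA replicate c. Fatty acid oxidation also did not pass without regular-diet sham replicate c (-0.45). Cytosolic ribosomal protein genes, fixed as a list of sample quality, were lower in 30 of 30 members, 0 of them adjusted over the list alone (median -0.44, adjusted p = 0.000101, adjusted p = 0.649 with an estimated correlation). Their median was -0.17 without regular-diet sham replicate a and -0.80 without regular-diet CIA replicate b.

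In total 22 of 40 lists passed with camera's preset correlation, 0 with an estimated correlation and 3 with fry. DESeq2 called 837 genes, limma voom 1 and an edgeR fit of only these groups 0. In edgeR 81 genes passed with the mean of the adipocyte list as a covariate and 0 with that of the muscle list, both chosen after the data were seen. The authors' deposited table has 445 genes at a q-value under 0.05, which include all 4. The edgeR count was 0, 1 and 0 without regular-diet sham replicate a, b or c, 2 and 16 without regular-diet CIA replicate b or c, and 12, 2 and 2 without high-fat CIA replicate a, b or c.

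The second comparison asked the same of mice on the high-fat diet, where 1610 genes passed in edgeR, 753 higher and 857 lower in CIA. Ccl2, which attracts monocytes, rose from 4.38 ± 0.908 to 113 ± 101 CPM (SD, n = 2 and 3, log2 fold change 4.69 ± 1.26 SE, adjusted p = 0.0437). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose from 1.10 ± 0.266 to 36.2 ± 17.4 CPM (5.04 ± 1.24, adjusted p = 0.0352). Clec4e, a pattern receptor of myeloid cells, rose as well (6.46 ± 1.53, adjusted p = 0.0329). Lep, which encodes the satiety hormone leptin, fell from 454 ± 25.0 to 43.7 ± 23.2 CPM (-3.38 ± 0.68, adjusted p = 0.0228). Adipoq, which encodes adiponectin, fell from 1421 ± 175 to 292 ± 183 CPM (-2.28 ± 0.64, adjusted p = 0.0487). Retnla (-4.30 ± 1.01, adjusted p = 0.0319) and Ccl24 (-3.75 ± 0.81, adjusted p = 0.0264), markers of alternatively activated macrophages, fell too.

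Chemokines rose as a list, 5 of 22 members over all genes, and 16 higher and 1 lower adjusted over the list alone (median 3.11, adjusted p = 0.000129, adjusted p = 0.531 with an estimated correlation). Among them were Ccl8 (4.27 ± 0.72, adjusted p = 0.0185) and the B cell attractant Cxcl13 (3.18 ± 0.86, adjusted p = 0.0444). Inflammatory cytokines were higher in 17 of 17 members, 1 over all genes and 10 adjusted over the list alone (median 3.71, adjusted p = 0.000132, adjusted p = 0.531 with an estimated correlation). The cytokine median was 2.96 with the 2 members that had no count in a group set to the bound of 3 counts. Il1b, at 6.29 ± 1.92, did not pass (adjusted p = 0.0616), and Il6 stood at 52.6, 3.56 and 103 CPM in high-fat CIA and 0.0534 and 0.117 in high-fat sham. Neutrophil markers rose, 2 of 15 over all genes and 9 adjusted over the list alone (median 4.15, adjusted p = 4.73e-06, adjusted p = 0.531 with an estimated correlation). T and natural killer cell markers rose, 4 of 19 over all genes and 8 adjusted over the list alone (median 1.84, adjusted p = 4.73e-06, adjusted p = 0.531 with an estimated correlation), for example Il2rb (1.94 ± 0.41, adjusted p = 0.0260). In high-fat sham the mean log2 CPM was -0.78 for the T and natural killer cell list and 0.635 for the cytokine list, which is low. The neutrophil median was 7.46 without high-fat sham replicate a, where the marrow granulocyte gene Mpo stood at 173 CPM against 0.817 in replicate b.

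Matrix genes and the enzymes that cut matrix rose together. Collagen and matrix genes rose, 5 of 22 over all genes and 14 adjusted over the list alone (median 1.55, adjusted p = 1.35e-05, adjusted p = 0.531 with an estimated correlation). Among them were Col12a1, a fibril-associated collagen (3.87 ± 0.85, adjusted p = 0.0272), and Loxl2, which crosslinks collagen (1.60 ± 0.37, adjusted p = 0.0306). Matrix-degrading proteases and inhibitors rose, 5 of 19 over all genes and 9 adjusted over the list alone (median 1.80, adjusted p = 0.000236, adjusted p = 0.531 with an estimated correlation). The aggrecan-cutting Adamts4 rose from 6.04 ± 0.459 to 108 ± 65.1 CPM (4.15 ± 0.98, adjusted p = 0.0319), with the cathepsin Ctss (2.04 ± 0.41, adjusted p = 0.0226) and Adamts12 (1.97 ± 0.28, adjusted p = 0.0173). Mmp3 (4.22 ± 1.68, adjusted p = 0.123) and Mmp13 (4.30 ± 1.36, adjusted p = 0.0669) did not pass.

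Interferon response genes rose on the high-fat diet, 7 of 20 over all genes and 10 adjusted over the list alone (median 1.08, adjusted p = 0.000464, adjusted p = 0.583 with an estimated correlation). MHC class II genes rose, 2 of 10 over all genes and 6 adjusted over the list alone (median 0.98, adjusted p = 0.000181, adjusted p = 0.531 with an estimated correlation), among them their master regulator Ciita (2.29 ± 0.43, adjusted p = 0.0208). The interferon median was 0.46 without high-fat CIA replicate b. Selp, by which endothelium catches leukocytes, rose (4.16 ± 0.72, adjusted p = 0.0185).

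Fat cell and lipid genes fell in CIA on the high-fat diet. Adipocyte markers fell, 5 of 17 over all genes and 11 adjusted over the list alone (median -1.94, adjusted p = 4.73e-06, adjusted p = 0.531 with an estimated correlation), including Pparg, the master regulator of fat cells (-2.05 ± 0.47, adjusted p = 0.0310). Lipolysis and lipid droplet genes fell, 3 of 17 over all genes and 10 adjusted over the list alone (median -1.61, adjusted p = 5.50e-05, adjusted p = 0.531 with an estimated correlation), including the lipase Lipe (-2.02 ± 0.57, adjusted p = 0.0486). Fatty acid oxidation genes fell, 6 of 21 over all genes, and 1 higher and 9 lower adjusted over the list alone (median -1.04, adjusted p = 0.000129, adjusted p = 0.583 with an estimated correlation), for example Hadh (-1.73 ± 0.45, adjusted p = 0.0409). Oxidative phosphorylation genes fell, 2 of 24 over all genes and 3 adjusted over the list alone (median -0.65, adjusted p = 6.23e-05, adjusted p = 0.583 with an estimated correlation). Skeletal muscle genes moved with them, 0 of 24 over all genes and 0 adjusted over the list alone (median -2.40, adjusted p = 0.000957, adjusted p = 0.607 with an estimated correlation). Their median was -1.31 without high-fat sham replicate b and -4.08 without high-fat CIA replicate c. Erythroid genes fell, 0 of 12 over all genes and 0 adjusted over the list alone (median -2.39, adjusted p = 0.0345, adjusted p = 0.713 with an estimated correlation). Their median was 1.70 without high-fat sham replicate a and -4.10 without high-fat CIA replicate b, and the list did not pass without regular-diet CIA replicate b (-2.39), high-fat CIA replicate a (-1.89) or high-fat sham replicate a.

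In total 24 of 40 lists passed with the preset correlation, 0 with an estimated correlation and 11 with fry. DESeq2 called 3327 genes, an edgeR fit of only these groups 492 and edgeR with the replicate letter as a block 776. The authors' deposited table has 3488 genes at a q-value under 0.05, which include 1580 of the 1610. With the adipocyte list as a covariate 1137 genes passed, 729 higher and 408 lower, of which 381 are among the 1610, and with the muscle list 5 did. Higher genes also outnumbered lower ones in DESeq2 (1825 and 1502) and without regular-diet CIA replicate b (1945 and 1793) or high-fat CIA replicate c (557 and 517). The edgeR count was 0 without high-fat sham replicate a and 0 without b, so each gene named here as past the test rests on both. It was 529 and 624 without regular-diet sham replicate b or c, 792 and 3738 without regular-diet CIA replicate a or b, and 1046 and 355 without high-fat CIA replicate a or b.

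**Figure D2:**
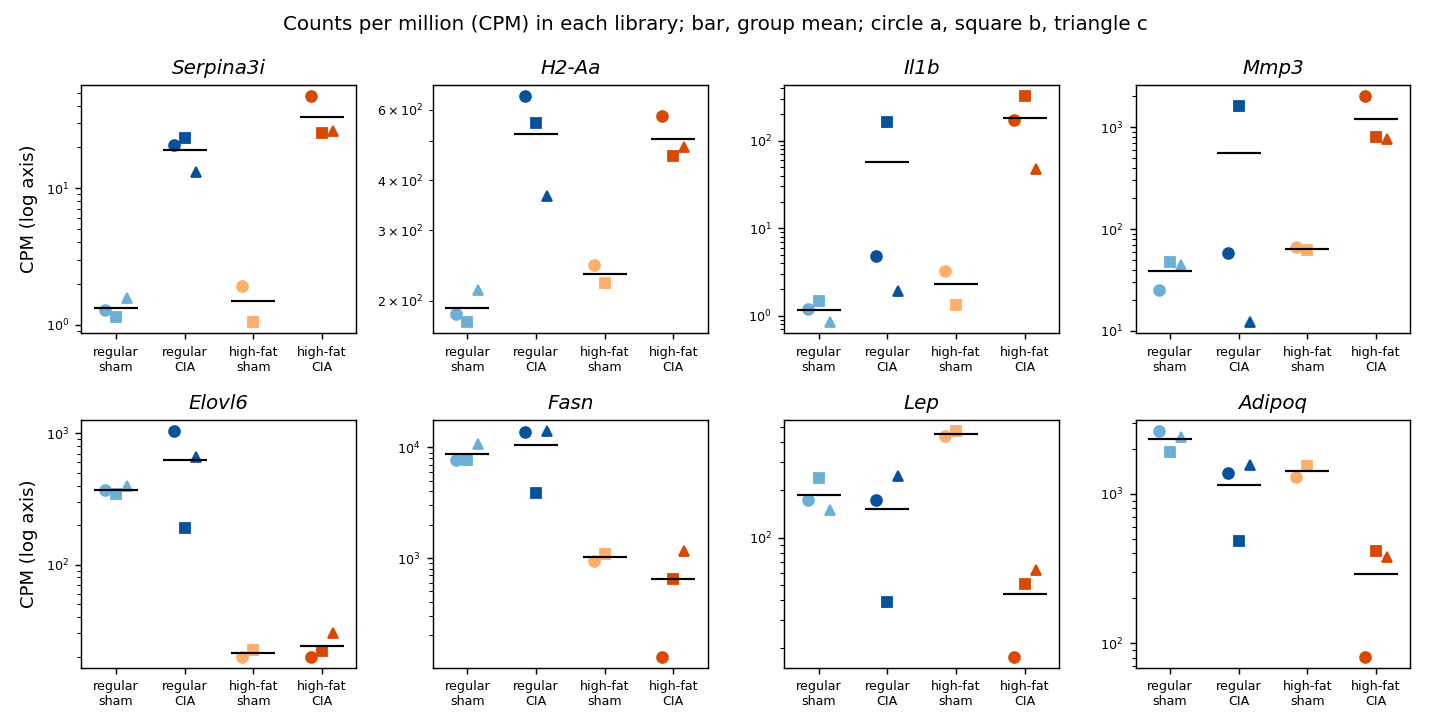
CPM (log axis) of 8 genes in each of the 11 libraries, by group, with a bar at the group mean and a symbol for each replicate letter. Il1b and Mmp3 in regular-diet CIA replicate b (163 and 1610) lie near the high-fat CIA libraries, and Elovl6 lies at 30.4 or below in all 5 high-fat libraries and at 191 or above in all 6 regular-diet ones.

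The third comparison asked what the high-fat diet changes in sham mice, and lipid-making and respiratory genes were lower as lists while 0 of 14892 single genes passed in edgeR. Fatty acid and triglyceride synthesis genes were lower in 18 of 19 members, 10 lower and 1 higher adjusted over the list alone (median -1.03, adjusted p = 4.97e-09, adjusted p = 0.735 with an estimated correlation). Fasn, which builds palmitate, stood at 8668 ± 1755 CPM on the regular diet and 1021 ± 116 on the high-fat diet (SD, n = 3 and 2, log2 fold change -3.09 ± 0.89 SE, adjusted p = 0.474). Its gene (ID 14104) lies on chromosome 11, 120805958 to 120825166 (GRCm38.p6). Elovl6, which lengthens palmitate and was chosen after its values were seen, had the smallest adjusted p (-4.12 ± 0.63, adjusted p = 0.341). Its gene (ID 170439) lies on chromosome 3, 129532386 to 129638495 (GRCm38.p6), and it stood at 367, 345 and 396 CPM on the regular diet and 20 and 22.5 on the high-fat diet. Lep stood at 187 ± 45.5 CPM on the regular and 454 ± 25.0 on the high-fat diet (1.28 ± 0.65, adjusted p = 0.680).

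Other metabolic lists moved with fat synthesis in sham mice. Fatty acid oxidation genes were lower in 20 of 21 members, 0 adjusted over the list alone (median -0.73, adjusted p = 1.77e-06, adjusted p = 0.735 with an estimated correlation). Oxidative phosphorylation genes were lower in 24 of 24 members, 9 adjusted over the list alone (median -0.73, adjusted p = 1.39e-15, adjusted p = 0.735 with an estimated correlation), and adipocyte markers in 16 of 17, 0 adjusted over the list alone (median -0.83, adjusted p = 0.00205, adjusted p = 0.735 with an estimated correlation). Macrophage and connective tissue markers rose as lists. Macrophage and monocyte markers were higher in 16 of 17 members, 3 adjusted over the list alone (median 0.89, adjusted p = 5.05e-08, adjusted p = 0.297 with an estimated correlation), with lysozyme, Lyz2, at 1.08 ± 0.36, adjusted p = 0.508. In high-fat sham replicate a their mean log2 CPM was 6.20 against 5.66 in replicate b, and Mpo, of marrow granulocytes, stood at 173 against 0.817 CPM. Markers of marrow granulocyte precursors (11 of 11 higher, median 3.12, adjusted p = 0.218) and neutrophils (15 of 15, median 1.49, adjusted p = 0.134) did not pass. Collagen and matrix genes (21 of 22 higher, median 0.54, adjusted p = 1.32e-05, adjusted p = 0.735 with an estimated correlation), tenocyte markers (10 of 10, median 1.33, adjusted p = 0.00205, adjusted p = 0.735 with an estimated correlation) and chondrocyte markers (14 of 14, median 1.59, adjusted p = 6.12e-05, adjusted p = 0.735 with an estimated correlation) had 0 members past the test adjusted over the list alone. Acan, a cartilage proteoglycan, had 2.80 ± 0.93, adjusted p = 0.508.

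Osteoblast markers rose, 0 of 12 adjusted over the list alone (median 1.57, adjusted p = 0.00301, adjusted p = 0.735 with an estimated correlation), with a median of 0.77 without high-fat sham replicate a. Lining fibroblast markers rose, 0 of 10 adjusted over the list alone (median 0.69, adjusted p = 0.0127, adjusted p = 0.735 with an estimated correlation), but did not pass without high-fat sham replicate b (0.44). Prg4, the joint lubricant gene of lining cells, had 1.13 ± 0.47, adjusted p = 0.588. Inflammatory cytokines (median 0.35, adjusted p = 0.0731) and chemokines (median 0.13, adjusted p = 0.113) did not pass. In total 14 lists passed with the preset correlation, 0 with an estimated correlation and 0 with fry. At an unadjusted p under 0.05 there were 1165 genes, DESeq2 called 121, limma voom 0 and an edgeR fit of only these groups 441. The edgeR count was 6 without regular-diet CIA replicate b and 31 with the adipocyte list as a covariate, and the authors' deposited table has 1372 genes at a q-value under 0.05.

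The fourth comparison asked how the diets differ once mice have CIA, and 588 genes passed in edgeR, 157 higher and 431 lower on the high-fat diet. Elovl6 fell from 631 ± 426 to 24.1 ± 5.57 CPM (SD, n = 3 in each group, log2 fold change -4.71 ± 0.54 SE, adjusted p = 0.0330). Fasn fell from 10590 ± 5825 to 648 ± 518 CPM (-4.03 ± 0.78, adjusted p = 0.0346). The lipogenic regulator Thrsp (-4.57 ± 0.98, adjusted p = 0.0394) and the oxytocin receptor Oxtr (-5.33 ± 0.60, adjusted p = 0.0330) fell as well. Ccr1, a chemokine receptor of myeloid cells, rose from 20.7 ± 5.95 to 108 ± 53.9 CPM (2.38 ± 0.43, adjusted p = 0.0333). The growth factor Ereg (2.59 ± 0.52, adjusted p = 0.0349) and Aldh1a2, which makes retinoic acid (2.68 ± 0.54, adjusted p = 0.0349), rose too.

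Fat synthesis and oxidation genes fell together on the high-fat diet in CIA mice. Fatty acid and triglyceride synthesis genes fell, 12 of 19 over all genes and 17 adjusted over the list alone (median -2.51, adjusted p = 4.07e-11, adjusted p = 0.503 with an estimated correlation), such as Acss2 (-4.10 ± 0.65, adjusted p = 0.0330) and Me1 (-3.59 ± 0.58, adjusted p = 0.0330). Fatty acid oxidation genes fell, 8 of 21 over all genes, and 1 higher and 18 lower adjusted over the list alone (median -1.30, adjusted p = 1.13e-08, adjusted p = 0.503 with an estimated correlation). Examples are Hadh (-2.11 ± 0.42, adjusted p = 0.0351) and Cpt2, which readies fatty acids for oxidation inside mitochondria (-1.34 ± 0.28, adjusted p = 0.0375). Oxidative phosphorylation genes fell, 1 of 24 over all genes (Ndufs3, -0.92 ± 0.18, adjusted p = 0.0346) and 17 adjusted over the list alone (median -0.78, adjusted p = 4.33e-08, adjusted p = 0.503 with an estimated correlation). Adipocyte markers moved with these lists, 3 of 17 lower over all genes and 17 adjusted over the list alone (median -1.99, adjusted p = 2.56e-09, adjusted p = 0.503 with an estimated correlation). Lipolysis genes fell, 0 of 17 over all genes and 11 adjusted over the list alone (median -1.74, adjusted p = 3.45e-06, adjusted p = 0.503 with an estimated correlation). Lep (-1.80 ± 0.61, adjusted p = 0.114) and Adipoq (-1.97 ± 0.59, adjusted p = 0.0829) did not pass.

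Macrophage, matrix and protease genes rose on the high-fat diet in CIA mice. Macrophage markers rose, 2 of 17 over all genes and 2 adjusted over the list alone (median 0.85, adjusted p = 0.00111, adjusted p = 0.503 with an estimated correlation), namely the integrin Itgam (1.80 ± 0.40, adjusted p = 0.0405) and Lyz2 (1.44 ± 0.33, adjusted p = 0.0437). Proteases and inhibitors rose, 3 of 19 over all genes and 5 adjusted over the list alone (median 1.09, adjusted p = 4.34e-06, adjusted p = 0.188 with an estimated correlation). The proteases past the test were Ctss (1.76 ± 0.35, adjusted p = 0.0346), Ctsk (2.08 ± 0.43, adjusted p = 0.0360) and Adamts1 (1.56 ± 0.33, adjusted p = 0.0389). Collagen and matrix genes were higher in 22 of 22 members, 1 over all genes and 6 adjusted over the list alone (median 1.07, adjusted p = 2.56e-09, adjusted p = 0.503 with an estimated correlation). Inflammatory cytokines rose, 0 of 17 over all genes and 0 adjusted over the list alone (median 1.37, adjusted p = 1.73e-05, adjusted p = 0.503 with an estimated correlation). Chemokines rose, 1 of 22 over all genes, and 4 higher and 1 lower adjusted over the list alone (median 1.49, adjusted p = 0.00226, adjusted p = 0.503 with an estimated correlation). Without regular-diet CIA replicate b the medians of proteases, matrix genes, cytokines and chemokines were 1.90, 1.72, 3.81 and 2.30.

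Neutrophil markers rose on the high-fat diet in CIA mice, 0 of 15 over all genes and 0 adjusted over the list alone (median 2.33, adjusted p = 5.26e-05, adjusted p = 0.505 with an estimated correlation). Their median was 1.04 without high-fat CIA replicate b, where Mpo stood at 236 CPM. Immediate early genes, fixed as a list of sample quality, rose too, 12 of 15 higher and 0 adjusted over the list alone (median 0.46, adjusted p = 0.0133, adjusted p = 0.639 with an estimated correlation). Their median was 1.16 without regular-diet CIA replicate b, and they did not pass without regular-diet CIA replicate a (0.21) or c (0.25) or high-fat CIA replicate b (0.06). The interferon (median 0.03, adjusted p = 0.833) and MHC class II lists (median -0.04, adjusted p = 0.833) did not pass. In total 18 lists passed with the preset correlation, 0 with an estimated correlation and 3 with fry. DESeq2 called 2006 genes, limma voom 297, an edgeR fit of only these groups 0 and edgeR with the replicate letter as a block 0. The fits of only the groups compared thus gave more diet genes in sham (441) than in CIA mice, the reverse of the main fit. With the adipocyte list as a covariate 130 genes passed, 116 higher and 14 lower, of which 8 are among the 588, and with the muscle list 0 did. The authors' deposited table has 695 genes at a q-value under 0.05, which include 483 of the 588. The edgeR count was 0 without any single one of the 3 regular-diet sham, 2 high-fat sham or 3 high-fat CIA libraries and without regular-diet CIA replicate a or c. It was 3224 without regular-diet CIA replicate b, so each gene named here as past the test rests on each of the 10 other libraries.

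**Figure D3:**
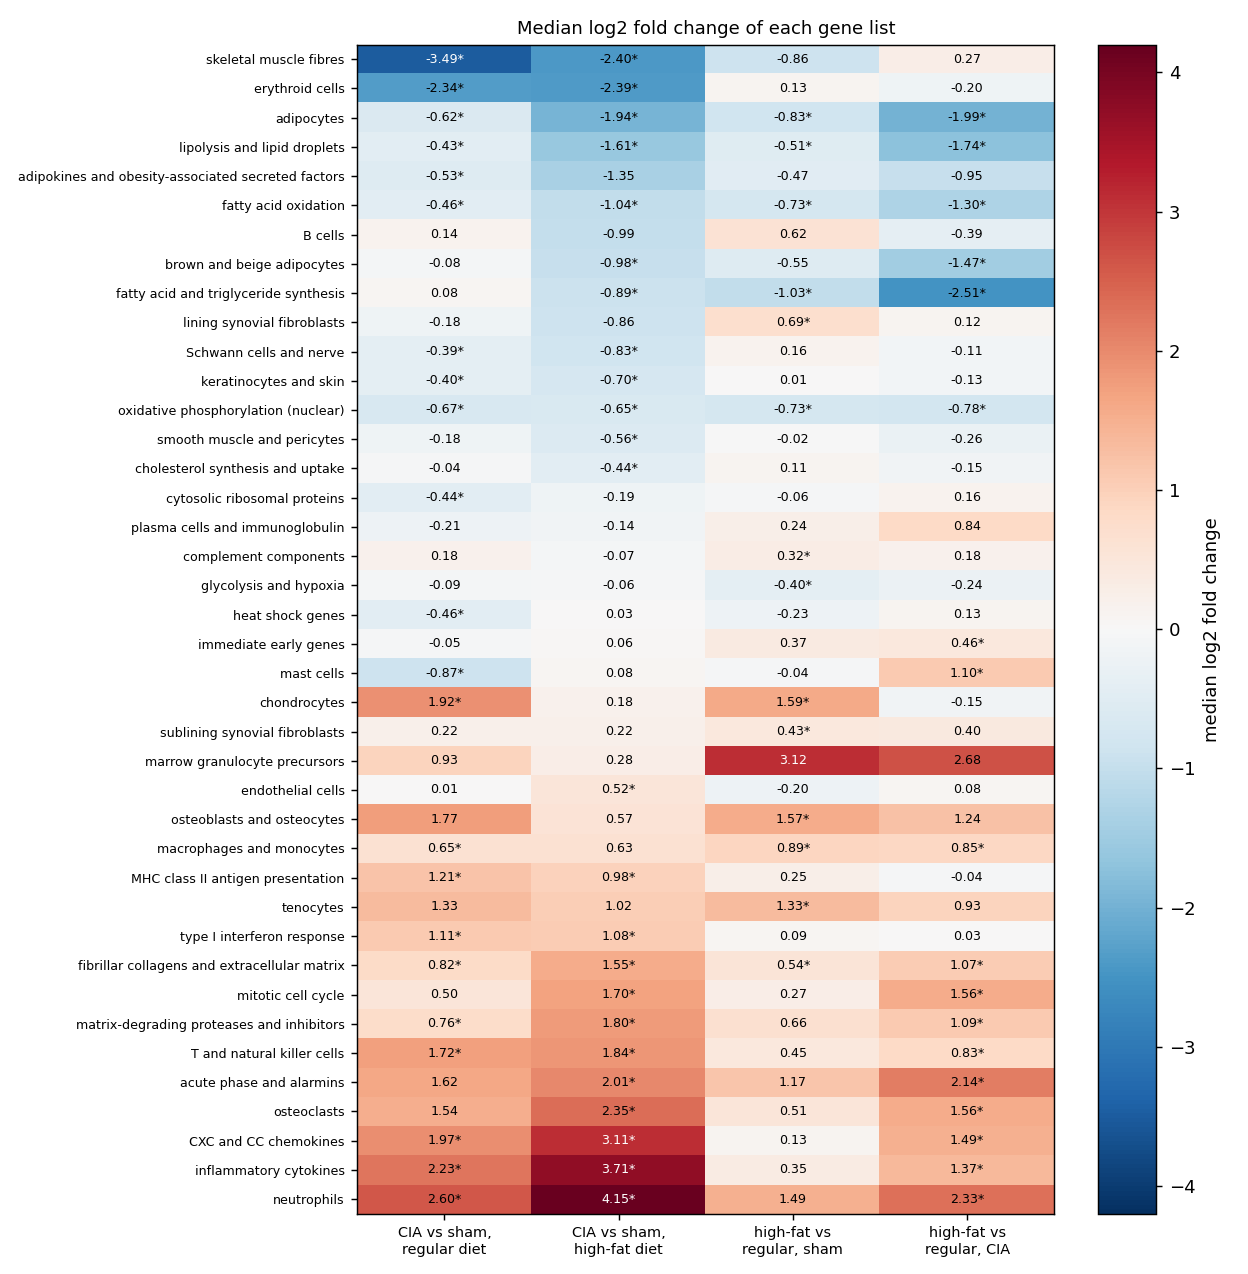
Median log2 fold change of the members of each of the 40 tested gene lists (1 line each) in 4 comparisons, with an asterisk where camera with its preset correlation gave an adjusted p under 0.05. Fatty acid and triglyceride synthesis genes have medians of -1.03 and -2.51 between the diets in sham and CIA mice, and neutrophil markers medians of 2.60 and 4.15 between CIA and sham on the regular and high-fat diets.

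The last comparison asked whether the diet changes the effect of CIA, as the effect on the high-fat diet minus that on the regular diet. Adipocyte markers had a more negative CIA effect on the high-fat diet, as a list (median -1.15, adjusted p = 1.55e-05, adjusted p = 0.699 with an estimated correlation), and the median was -0.70 without high-fat CIA replicate a. Proteases and inhibitors had a more positive one (median 0.51, adjusted p = 0.000615, adjusted p = 0.254 with an estimated correlation), with medians of 0.33 without regular-diet sham replicate b and 1.04 without regular-diet CIA replicate b. Mast cell markers (median 1.05, adjusted p = 0.000615, adjusted p = 0.185 with an estimated correlation) and endothelial markers (median 0.34, adjusted p = 0.00571, adjusted p = 0.620 with an estimated correlation) had positive differences too. The mast cell medians for CIA against sham were -0.87 on the regular and 0.08 on the high-fat diet, where the list did not pass (adjusted p = 0.958). Over all genes 0 members of these 4 lists passed. They are among 16 of 40 lists that passed with the preset correlation, 0 of which did so with an estimated correlation and 0 with fry. Adjusted over the list alone, 0, 1, 0 and 0 of their members passed.

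Lep had a log2 difference of -3.08 ± 0.89 (adjusted p = 0.989) and Adipoq of -1.26 ± 0.86 (adjusted p = 0.989), the latter -0.82 without high-fat CIA replicate a. In edgeR 0 of 14892 genes passed, 635 had an unadjusted p under 0.05, DESeq2 called 21 and limma voom 0. The CIA effects on both diets, which share no library, had a Pearson r of 0.768 and a Spearman rho of 0.750 across 14892 genes, which are not independent replicates. They had the same sign in 77.8% of the genes, and in 1577 of the 1610 that passed on the high-fat diet. Regular-diet CIA replicate b lay at 47.3 on the first principal component, among the high-fat CIA libraries. These values were not computed without that library, so how far the agreement rests on it was not tested. The diet effects in sham and CIA mice, which share no library either, had r = 0.546 and rho = 0.526, with the same sign in 68.7% of the genes. Of the 588 genes that passed in CIA mice, 559 had the same sign in sham mice.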

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

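The tests of adipocyte share, scaling, a wrong label, depth and muscle tissue were chosen after the results they concern were seen, while the other splits of the samples were planned.

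Fatty acid and triglyceride synthesis genes fell as a list on the high-fat diet with camera's preset correlation in sham (median log2 fold change -1.03, adjusted p = 0.735 with an estimated correlation, fry adjusted p = 0.648) and in CIA mice (-2.51, adjusted p = 0.503 with an estimated correlation, fry adjusted p = 0.0408), and adipocyte markers moved with them (-0.83 and -1.99). The weakest median over 5 ways of scaling the libraries was -0.87 in sham and -2.39 in CIA mice, which argues against scaling as the cause. If a smaller share of adipocytes lowers both lists alike, the synthesis score minus the adipocyte score stays the same. In sham mice it was lower on the high-fat diet by more than its spread (difference -0.65, from -0.87 ± 0.0570, n = 3, to -1.52 ± 0.0872, n = 2, SD). Under that premise this argues against adipocyte share as the whole cause there. From sham to CIA, however, the adipocyte score fell while this value rose, from -0.87 to -0.27 on the regular and from -1.52 to -0.49 on the high-fat diet. The lists thus do not always fall alike. In CIA mice the diets differed by -0.22 (from -0.27 ± 0.194 to -0.49 ± 0.591, SD, n = 3 in each group), so fewer adipocytes and less synthesis per adipocyte cannot be told apart, because the spread exceeds the difference. Replicates a, b and c stood at -0.09, -0.25 and -0.48 in regular-diet and 0.15, -1 and -0.62 in high-fat CIA. High-fat CIA b and c thus lay below all regular-diet CIA libraries, and a, with the lowest adipocyte score (5.358), above them. A response of lipid synthesis to the diet may be the cause in sham mice and stays open as a hypothesis, since the diets' makeup was not tested.

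Regular-diet CIA replicate b lay apart from replicates a and c, with 163 CPM of Il1b against 4.8 and 1.93. If it were a high-fat CIA library under a wrong label, its score over the 50 genes with the smallest p for diet in sham libraries would lie among those of high-fat CIA. It was -2.39, which is -0.80 from the lowest of the high-fat CIA scores of -1.38, -1.58 and -1.44, and replicates a and c were at -2.89 and -2.88, which argues against that label error. Its total of 14319731 counts lies within the range of the other libraries, which argues against depth. A stronger arthritis in the tissue of that library may account for it, which no label here can test, so this stays open.

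Skeletal muscle genes were lower in CIA on the regular diet (median -3.49, adjusted p = 0.000532, adjusted p = 0.649 with an estimated correlation), and adjacent muscle in single sham samples is a candidate source. Without regular-diet sham replicate c the median was 0.39, and that library held 144 CPM of Acta1, 93.1 of Ckm and 119 of Tnnt3, against 0.954, 0 and 1.27 in replicate a and 1.02, 0 and 0.889 in b. The values the explanation needs are there, so the fall may reflect muscle in that 1 sample. All 24 tested members of this list are muscle fibre markers. Their mean log2 CPM was -0.043, 0.048 and 4.883 in regular-diet sham replicates a, b and c. It was -0.015, 0.24 and 0.018 in regular-diet CIA, so outside sham replicate c there was no fall on this diet. Those levels are near the floor, so whether the disease itself lowers these genes stays open.

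Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For CIA against sham on the regular diet 1 of the 10 splits, the real one, gave as many genes (4, highest other 0), and for diet in CIA mice also 1 of 10 (588, highest other 132).

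Gene lists stood out because camera's test of the interaction, the CIA effect on the high-fat diet minus that on the regular diet, passed with the preset correlation. Lists with a positive median difference were mitotic cell cycle genes (1.18, adjusted p = 4.12e-06), inflammatory cytokines (0.84, adjusted p = 0.00173), collagen and matrix genes (0.50, adjusted p = 0.00140), neutrophil markers (0.51, adjusted p = 0.00173), osteoclast markers (1.07, adjusted p = 0.00173), acute phase genes and alarmins (0.42, adjusted p = 0.0173) and chemokines (0.76, adjusted p = 0.0201). Each of these 7 had adjusted p = 0.699 with an estimated correlation. Proteases and inhibitors (0.51, adjusted p = 0.000615), mast cell markers (1.05, adjusted p = 0.000615) and endothelial markers (0.34, adjusted p = 0.00571) were positive too. These had adjusted p = 0.254, 0.185 and 0.620 with an estimated correlation. Negative medians were found for markers of adipocytes (-1.15, adjusted p = 1.55e-05) and chondrocytes (-1.59, adjusted p = 0.0233) and for fatty acid and triglyceride synthesis (-0.95, adjusted p = 0.000615), lipolysis (-0.79, adjusted p = 0.00340), fatty acid oxidation (-0.52, adjusted p = 0.00340) and cholesterol synthesis and uptake (-0.28, adjusted p = 0.00571). All 6 had adjusted p = 0.699 with an estimated correlation. In edgeR 0 single genes passed in this contrast, 635 had an unadjusted p under 0.05, and DESeq2 called 21, 9 positive and 12 negative.

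Of these 16 lists, 9 did not pass, or changed sign, without certain single libraries, given here with the median without them. For mitotic genes this was high-fat sham b (0.49). For neutrophil markers these were regular-diet sham b (-0.45), high-fat sham b (-0.46), high-fat CIA b (-0.45). For osteoclast markers these were high-fat sham b (0.82), high-fat CIA a (0.17). For lipolysis genes these were regular-diet CIA c (-0.47), high-fat CIA a (-0.51). For fatty acid oxidation these were regular-diet CIA a (-0.40) and c (-0.23), high-fat CIA a (-0.41). For cholesterol genes these were regular-diet CIA a (-0.02), high-fat CIA b (-0.03). For acute phase genes these were regular-diet sham a (0.31) and b (0.38), regular-diet CIA a (0.08), high-fat sham b (-0.17), high-fat CIA b (-0.25) and c (0.62). For chemokines these were regular-diet sham a (0.77) and b (0.65), regular-diet CIA a (0.75) and c (0.68). For chondrocyte markers these were regular-diet sham b (-1.55), regular-diet CIA b (-1.54) and c (-0.15), high-fat CIA a (-1.18). Neutrophil markers passed without regular-diet sham replicate b and acute phase genes without high-fat CIA replicate b, but with opposite medians of -0.45 and -0.25.

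Other single libraries moved the median of a list by over 1.5 times and left it past the test. This held for mitotic genes without regular-diet CIA b (2.21), high-fat sham a (3.42), high-fat CIA a (0.13), and for adipocyte markers without high-fat CIA a (-0.70). It also held for fatty acid and triglyceride synthesis without regular-diet CIA a (-0.61), high-fat CIA a (-0.50) and c (-1.43), and for proteases and inhibitors without regular-diet sham b (0.33), regular-diet CIA b (1.04). This held for collagen and matrix genes without regular-diet CIA b (0.99) and c (0.25), and for inflammatory cytokines without regular-diet CIA a (0.40), b (3.83), c (0.39), high-fat CIA b (0.02). It also held for neutrophil markers without regular-diet sham a (0.80) and c (0.96), regular-diet CIA b (2.33), high-fat sham a (4.74), high-fat CIA c (0.95), and for lipolysis genes without high-fat CIA b (-1.34). This held for fatty acid oxidation without regular-diet CIA b (-0.87), and for cholesterol genes without regular-diet CIA b (-0.53), high-fat CIA a (-0.60). It also held for acute phase genes without regular-diet sham c (0.65), regular-diet CIA b (0.81) and c (0.19), high-fat sham a (2.88), and for chemokines without regular-diet CIA b (1.70).

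The 96 named genes, many named because they passed a contrast, were searched for opposite effects of diet or of CIA without overlap of libraries. A pair of protease genes met this: every library of one diet lay on one side in sham mice and on the opposite side in CIA mice. With 3 against 3 libraries, 10% of genes not chosen on these data separate by chance in a single comparison. With 3 against 2, as between the diets in sham mice, the share is larger. A few such genes may therefore arise by chance. Adamts1 had a log2 fold change between diets of -0.71 in sham and 1.56 in CIA mice, a difference of 2.28 (interaction, edgeR adjusted p = 0.919). Adamts12 had -0.58 in sham and 0.69 in CIA mice, a difference of 1.26 (adjusted p = 0.989), so neither difference passed. Groups of 2 or 3 libraries are too small for a rule on single outlying samples, so none was applied.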

How the results depend on the processing

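The adipocyte and muscle covariates and the averages over diets or over CIA were chosen after the data were seen, and all other alternatives were planned. Of 162 named gene results under up to 22 alternatives, 2621 values kept direction and side of the threshold, 849 no longer passed, 50 newly passed and 5 changed sign. Of 94 called list results, 1238 values kept both, 259 no longer passed and 7 changed sign. RLE and upper-quartile scaling, both filters, leaving out the 20 most abundant genes and limma on log2(FPKM + 1) kept all 7 counts of genes within 1.5 times, though not always the balance of higher and lower genes. The cause of the shifts below was not tested, unless stated.

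DESeq2 called 837 and 3327 genes for CIA on the regular and high-fat diet, 121 and 2006 for diet in sham and CIA mice, 21 for the interaction and 2131 for diet averaged over sham and CIA. With limma voom the counts were 1 for CIA on the regular diet and 297 for diet in CIA mice, and limma on log2(FPKM + 0.1) called 8 for CIA on the regular diet. A fit of only the groups compared, each with its own estimate of the spread, called 0, 492, 441 and 0 in the order above. It was not run for the interaction and the averages, which need all 4 groups. The main fit, which shares the spread over all groups, instead called 0 and 588 for diet in sham and CIA mice. The authors' table has 1372 and 695. Between replicates the chi-square per degree of freedom was 19.1 to 51.3 within sham groups and 30.3 to 278.5 within CIA groups. Whether sham or CIA mice show more diet genes thus depends on the fit. The threshold on the fold left 397 for averaged diet and 1469 for averaged CIA. With the adipocyte covariate the counts were 81 for CIA on the regular diet, 1137 for CIA on the high-fat diet, of which 381 are among the 1610, 31 for diet in sham and 130 for diet in CIA mice, 8 of them among the 588, 1047 for averaged diet and 3236 for averaged CIA. With the muscle covariate they were 0 and 5 for CIA on the regular and high-fat diet and 0 for diet in CIA mice, 239 for averaged diet and 742 for averaged CIA. With an estimated correlation 0 lists passed in each of the 5 contrasts, and with fry 3, 11, 0, 3 and 0 did.

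The labels do not say whether letters pair the samples. Deviations from group means correlated at -0.426 to 0.463 in 15 same-letter pairs, 5 of them over 0.1. Their median was -0.037, against 0.0435 for pairs of different letters. Deviations within a small group depend on each other and outlying libraries weigh on them, so this cannot exclude pairing. With the replicate block the counts were 5 and 776 for CIA on the regular and high-fat diet, 0 and 0 for diet in sham and CIA mice, 0 for the interaction, 0 for averaged diet and 2623 for averaged CIA.

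Leaving out 1 library gave 0 to 16 genes for CIA on the regular diet, 0 to 3738 on the high-fat diet, 0 to 6 for diet in sham, 0 to 3224 for diet in CIA mice, 0 for the interaction, 0 to 2891 for averaged diet and 2 to 4347 for averaged CIA. The lists that passed numbered 14 to 25, 21 to 24, 14 to 25, 18 to 26 and 12 to 23 in the 5 contrasts. Where 1 high-fat sham library is left, it is assumed to vary like the other groups. For CIA on the regular diet Mmp3 (-0.15 to 4.32), Lep (-0.85 to 0.15) and Atp5b (-0.57 to 0.16) changed sign without regular-diet CIA replicate b, and Acta1 (-6.51 to 0.39) and the skeletal muscle list (-4.38 to 0.39) without regular-diet sham replicate c. Without high-fat sham replicate a S100a8 changed sign between diets in sham (-2.30 to 3.32), and the erythroid list for CIA on the high-fat diet (-4.10 to 1.70). In the interaction the neutrophil list (-0.46 to 4.74) was at -0.45, -0.46 and -0.45 without replicate b of regular-diet sham, high-fat sham or high-fat CIA, and acute phase genes (-0.25 to 2.88) at -0.17 and -0.25 without the latter pair. With 2 or 3 libraries per group, folds near 2 stayed mostly below detection in simulated counts. Larger folds can be missed too, as for Elovl6 between diets in sham mice.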

Other observations

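The averages over diets and over CIA, the enrichment tests and the genes named under them were chosen after the data were seen. Averaged over sham and CIA mice, 871 genes differed between the diets in edgeR, 251 higher and 620 lower on the high-fat diet, and 471 of them are among the 588 that passed in CIA mice. The steps from citrate to long-chain fatty acids fell together: Acly, which splits citrate (-2.28 ± 0.37, adjusted p = 0.0212), Acaca, which makes malonyl-CoA (-3.05 ± 0.51, adjusted p = 0.0223), Fasn (-3.56 ± 0.61, adjusted p = 0.0226), Elovl6 (-4.41 ± 0.43, adjusted p = 0.0139) and Scd1 (-3.17 ± 0.57, adjusted p = 0.0243). Of 19 synthesis genes 12 were lower over all genes, and 17 lower and 1 higher adjusted over the list alone (median -1.72, camera adjusted p = 7.88e-12, adjusted p = 0.522 with an estimated correlation). Of 24 oxidative phosphorylation genes 11 were lower over all genes and 22 adjusted over the list alone (median -0.77, camera adjusted p = 2.71e-12, adjusted p = 0.522 with an estimated correlation). Adipocyte markers fell with them, 17 of 17 lower, 4 over all genes and 15 adjusted over the list alone (median -1.42, camera adjusted p = 4.48e-08, adjusted p = 0.522 with an estimated correlation). With the adipocyte list as a covariate 1047 genes passed, 605 higher and 442 lower, of which 166 are among the 871, and with the muscle list 239 did. With the replicate letter as a block 0 genes passed. Higher genes on the high-fat diet, taken from several lists, were Ccr1 (2.08 ± 0.32, adjusted p = 0.0199), the complement receptor C3ar1 (1.07 ± 0.17, adjusted p = 0.0199), Ctss (1.33 ± 0.25, adjusted p = 0.0247) and Lyz2 (1.26 ± 0.24, adjusted p = 0.0247). Macrophage markers rose as a list, with 4 of 17 members higher over all genes and 10 adjusted over the list alone (median 0.89, camera adjusted p = 2.86e-06, adjusted p = 0.304 with an estimated correlation). The count was 8, 289 and 0 without regular-diet sham replicate a, b or c, 41, 2891 and 52 without regular-diet CIA replicate a, b or c, 0 and 0 without high-fat sham replicate a or b, and 407 without high-fat CIA replicate c.

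Averaged over the diets, 3542 genes differed between CIA and sham, 1929 higher and 1613 lower, and 1572 of them are among the 1610 that passed on the high-fat diet. Lower genes outnumbered higher ones with upper-quartile scaling (1848 and 1720), limma voom (1662 and 1570), limma on log2(FPKM + 1) (1781 and 1597) and on log2(FPKM + 0.1) (1746 and 1659), and without high-fat sham replicate a (636 and 600). Serpina3i (4.14 ± 0.30, adjusted p = 0.000586) passed without each of the 11 libraries in turn. MHC class II genes rose, with 10 of 10 past the test over all genes (median 1.07, camera adjusted p = 1.58e-06, adjusted p = 0.481 with an estimated correlation), H2-Aa at 1.28 ± 0.18, adjusted p = 0.00585 and Ciita at 2.46 ± 0.29, adjusted p = 0.00523. T and natural killer cell markers (11 of 19 higher over all genes, 15 adjusted over the list alone), chemokines (12 and 16 of 22), collagen and matrix genes (14 and 15 of 22) and proteases (11 and 13 of 19) rose as lists. Their camera adjusted p = 4.91e-07 to 0.00106, and adjusted p = 0.481 with an estimated correlation. Among genes that rose were the chemokine Ccl8 at 3.70 ± 0.46, adjusted p = 0.00523 and the monocyte chemokine receptor Ccr2 at 2.63 ± 0.35, adjusted p = 0.00562. Oxidative phosphorylation genes (14 of 24 lower over all genes, 16 adjusted over the list alone, median -0.65, camera adjusted p = 4.06e-07, adjusted p = 0.481 with an estimated correlation) and adipocyte markers (9 of 17 and 12, median -1.25, camera adjusted p = 9.17e-06, adjusted p = 0.500 with an estimated correlation) fell. Skeletal muscle genes fell with them, 24 of 24 lower, 11 over all genes and 17 adjusted over the list alone (median -2.96, camera adjusted p = 0.000258, adjusted p = 0.555 with an estimated correlation), although on the regular diet their median was 0.39 without regular-diet sham replicate c. Erythroid genes fell too, 3 of 12 over all genes and 4 adjusted over the list alone (median -2.41, camera adjusted p = 0.00274, adjusted p = 0.563 with an estimated correlation). With the adipocyte list as a covariate 3236 genes passed, of which 1514 are among the 3542, and with the muscle list 742, 338 higher and 404 lower. The count was 1967 and 2231 without regular-diet sham replicate a or b, and 1236 and 2 without high-fat sham replicate a or b.

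Among the KEGG terms that the deposited table gives (340 with 10 or more of 6207 background genes, one-sided Fisher's exact test), 18 were enriched among genes higher in CIA on the high-fat diet. They include TNF signaling (15 of 98, 5.72 expected, adjusted p = 0.0230) and Toll-like receptor signaling (12 of 71, 4.14 expected, adjusted p = 0.0273). NOD-like receptor signaling and infection terms such as Influenza A, Staphylococcus aureus infection and Measles ranked above both, each at adjusted p = 0.023. The enriched terms are thus not particular to arthritis. Among lower genes 17 terms passed, including degradation of valine, leucine and isoleucine (20 of 51, 2.86 expected, adjusted p = 2.94e-10) and peroxisome (20 of 79, 4.43 expected, adjusted p = 7.85e-07). For genes lower on the high-fat diet in CIA mice 32 terms passed, including the same branched-chain amino acid pathway (14 of 51, 1.68 expected, adjusted p = 8.83e-08), fatty acid metabolism (14 of 57, 1.88 expected, adjusted p = 2.94e-07) and the citrate cycle (7 of 29, 0.958 expected, adjusted p = 0.000921). For genes higher there 0 passed. Genes of one term are not independent, so these p-values describe the called genes only. Adipocyte markers fell as a list in both comparisons. With the adipocyte list as a covariate 408 lower genes passed for CIA on the high-fat diet, against 857 without it. For diet in CIA mice 14 did, against 431. These are largely other genes: of all that passed with the covariate, higher or lower, 381 of 1137 and 8 of 130 also passed without it. The adipocyte score did not overlap between the groups of either comparison. The covariate therefore cannot separate adipocyte share from CIA or diet. How far these metabolic terms reflect adipocyte share was not tested.

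Complement genes did not pass as a list in CIA on the high-fat diet (median -0.07, adjusted p = 0.989), yet the receptors C3ar1 (1.39 ± 0.26, adjusted p = 0.0210) and C5ar1 (2.40 ± 0.52, adjusted p = 0.0269) rose and C7, part of the membrane attack complex, fell (-3.16 ± 0.77, adjusted p = 0.0348). Osteoclast markers, of bone-resorbing cells, rose there (1 of 12 over all genes, 7 adjusted over the list alone, median 2.35, adjusted p = 0.000615, adjusted p = 0.531 with an estimated correlation), with a median of 1.30 without high-fat CIA replicate a. Mast cell markers rose on the high-fat diet in CIA mice (0 of 8 over all genes, 5 adjusted over the list alone, median 1.10, adjusted p = 0.00226, adjusted p = 0.207 with an estimated correlation). In CIA against sham they fell on the regular diet (3 lower and 1 higher adjusted over the list alone, median -0.87, adjusted p = 0.0127, adjusted p = 0.344 with an estimated correlation) and did not pass on the high-fat diet (median 0.08, adjusted p = 0.958). The regular-diet fall did not pass without regular-diet sham replicate c (-0.77) or regular-diet CIA replicate b (-0.49). The adipokine list in CIA on the regular diet had a median of -0.53 and a mean of 0.39, so its typical and average member differ in sign. Markers of B cells (median -0.99, adjusted p = 0.442), plasma cells (-0.14, adjusted p = 0.958) and marrow granulocyte precursors (0.28, adjusted p = 0.636) did not pass in CIA on the high-fat diet. The marrow score, a mean log2 CPM, was 5.80 in high-fat sham replicate a and 6.69 in high-fat CIA replicate b, and between -0.15 and 3.77 in the other libraries.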
